A study of Mus musculus with 36 samples.

How the data were processed

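Polyadenylated RNA was measured in mouse duodenal organoids from C57BL/6 mice, in 36 samples of 20 to 50 organoids each, harvested from a microfluidic chip after 24, 48 or 72 h of DAPT pulses with a period of 90, 130 or 170 min or of a DMSO control. Libraries were made with the Sort-seq method, which tags each molecule with a barcode (UMI), per the labels' protocols. Reads were aligned with STAR 2.7.8a and molecules counted with UMI-tools 1.1.1, per the submitters' processing notes. The deposited values are whole-number UMI counts per gene symbol and library, with no normalization by the authors apparent in them. The genome build, the annotation, the UMI length and the counting rule are not given in the sources used here, so genes carry the symbols of the deposited table and no coordinates are reported.

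All 36 libraries were mapped to a treatment, duration and replicate number through their column names, with 0 columns left over. The 4 treatments and 3 durations form 12 groups of 3 libraries. Total counts ran from 482741 to 1447330 with a median of 958749. At these totals counting error limits the precision of genes with few molecules, and the tests estimate the spread between samples from the replicates.

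Gene tests used edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, which left 11462 of 34197 and 22735 not tested. Normalization was by TMM, the model had 1 coefficient for each of the 12 groups (24 residual degrees of freedom), and quasi-likelihood F tests were robust. The biological coefficient of variation was 0.145. Adjusted p-values are Benjamini-Hochberg values over all tested genes with a threshold of 0.05, and the F tests of several coefficients have no direction while all others are two-sided. Changes are on the log2 scale with standard errors. The 21 comparisons were each period with DMSO and the periods with one another averaged over durations with equal weight, each period with DMSO at each duration, any difference among the 3 periods at each duration, the treatment by time interaction, and 48 and 72 h with 24 h averaged over treatments.

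Before the data were examined, 28 gene lists, the comparisons, the tests, the alternatives and the rule for naming genes were fixed. The lists were Notch targets and receptors, secretory progenitors, Lgr5 stem cells, Wnt targets, Paneth cells, goblet cells, enteroendocrine cells, tuft cells, enterocytes, villus tip enterocytes, villus bottom antimicrobial genes, S phase, G2 and M phase, M cells, fetal-like and YAP targets, interferon response, NF-kB and inflammatory genes, hypoxia and glycolysis, unfolded protein and integrated stress responses, p53 targets, immediate early and heat shock genes, cholesterol synthesis, PPAR and fatty acid oxidation, BMP targets, gastric or Brunner gland epithelium, fibroblasts, immune cells and endothelial cells. A list needed 3 tested members, which 25 had. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the 150 tests of treatments and, separately, the tests of durations. Each call was also computed with a correlation estimated per list and with fry, a rotation test of the list alone. In the models with pairs of libraries as blocks, list p-values were adjusted over the lists of each comparison alone, a smaller correction. In 28 of the 200 list tests the mean, the median and the test differed in sign, and 0 of those passed. Members were also adjusted over the list alone. A list score was the mean of log2(CPM + 1) over the tested members of a list, compared by an exact permutation of treatments within durations (8000 arrangements, two-sided, adjusted over 150 tests), and the interaction of scores by 100000 permutations. With 3 libraries against 3 an exact test cannot go below 0.1, so list scores were not tested at single durations.

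Genes were named by rule: in averaged comparisons up to 10 higher and 10 lower genes past the threshold with the same sign at every duration, for durations 6 and 6 with the same sign in every treatment, at single durations 3 and 3, and where none passed the 3 with the smallest p-values. Of these, 1 gene is not reported here. Up to 4 members per list past the threshold, and a panel of 19 markers, of which 17 were tested, were added; Nrarp and Neurog3 did not pass the filter. Of the panel, members not named in the results did not pass over all genes in the comparison described.

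The gene and list tests were tested on simulated data with the real means and library sizes, in which independent genes were changed by known amounts. For 90 min pulses against DMSO averaged over durations, 63.6% of genes changed 1.5-fold and 89.0% of those changed 2-fold were recovered among 11338 genes, and 4.40% of the calls were unchanged genes. For the same comparison at 24 h the shares were 20.4% and 52.5% among 11345 genes, with 5.26% of calls unchanged, and for 72 against 24 h 71.0% and 92.9% among 11344 genes, with 4.12%. A goblet list raised by 0.3 was recovered and 0 of the other lists were called. All genes were drawn independently there, so the list tests were not tried on genes that vary together. Replicates were checked for duplicates, with a chi-square per degree of freedom of 1.26 to 4.50 over 36 pairs.

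Other settings fixed in advance were RLE size factors, no filter on low counts, DESeq2 1.42.0, a replicate block, only the compared groups in the model, each library left out in turn (for list tests each replicate number), an estimated correlation, fry, a pseudocount of 10 CPM, log2 of the summed CPM of a list, and members with at least 10 counts. Chosen after the data were seen were log2 of the library total, the level of 4 Y-linked genes and Xist, and all 3 as covariates, leaving out the 2 libraries with the highest Xist level, averages over 48 and 72 h alone, a replicate block within duration for pairs of treatments (also averaged over 24 and 48 h, and with each pair left out of the gene and list tests), sign flips of same-numbered differences, counts thinned to the lowest total, list scores without each library, list tests of Paneth, enterocyte, villus bottom, S phase and G2 and M phase genes without the 1 to 4 libraries whose scores stand apart (with the same genes tested), and splits of 72 against 24 h that keep same-numbered libraries together. Covariates for sex-linked genes were CPM divided by the highest library. Same-numbered libraries were called paired where the correlation across genes of their deviations from the group means was above 0.1 in every pair. Imaging of the oscillations was not used here.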

Results

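Messenger RNA was counted in 36 libraries of mouse duodenal organoids, cultures grown from intestinal crypts that hold stem cells and their absorptive and secretory descendants. Each organoid sample was kept in a microfluidic chip under flow and received repeated pulses of DAPT, a gamma-secretase inhibitor that blocks Notch receptor cleavage, with a period of 90, 130 or 170 min, or a DMSO control. Each treatment was applied for 24, 48 or 72 h, with 3 replicates for each of the 12 combinations, so that each treatment had 9 libraries and each duration 12. The DAPT concentration differed with the period (1.38 µM at 90 min, 2 µM at 130 min and 2.6 µM at 170 min, where the labels also name 2 µM), so a difference between periods was also a difference in dose. Organoids had been passaged 3, 2 or 1 days before the 24, 48 or 72 h experiments. Total counts per library ran from 482741 to 1447330, with a median of 958749, and 11462 of the 34197 genes had enough counts to be tested. The mean total was 859263 (SD 211770) in DMSO, 1058610 (SD 200370) at 90 min, 855825 (SD 150659) at 130 min and 1093670 (SD 201182) at 170 min, with 9 libraries each. The labels do not say whether the DMSO control was pulsed, or with which period, so differences from DMSO cannot be assigned to DAPT rather than to the pulsing. They also do not say whether replicates came from separate cultures or animals, so the p-values measure the spread between these samples. The stated purpose of the series was to look for subtle shifts in cell type composition after the Notch-driven oscillations had been set to each period.

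Organoids given 90 min pulses were compared with DMSO, averaged over the 3 durations, to ask which cell type programmes differed at the shortest period. Genes of secretory progenitors, the precursors of goblet, Paneth and enteroendocrine cells, rose by a mean of 0.26 (log2) over 13 measured members, 11 of them higher, at an adjusted p of 1.92e-04 (adjusted p = 0.141 with an estimated correlation). Genes of goblet cells, the mucus-secreting cells, rose by a mean of 0.27 with 22 of 23 members higher, at an adjusted p of 1.11e-08 (adjusted p = 0.380 with an estimated correlation). In the secretory progenitor list, Dll4, a Notch ligand, rose by 0.54 (SE 0.14) and was the 1 member that passed adjusted over the list alone. In the goblet list 3 members passed adjusted over the list alone, all upward, among them Fer1l6 at 0.83 (SE 0.22), Ramp1 at 0.63 (SE 0.17) and Creb3l4, a transcription factor, at 0.40 (SE 0.13). Hes1, a repressor switched on directly by Notch, averaged 298 CPM (SD 30.5, n = 9) after 90 min pulses and 347 CPM (SD 53.1, n = 9) in DMSO. Its change of -0.21 (SE 0.08) passed adjusted over the list alone and not over all genes. Mean Hes1 at 24 h was 280 CPM (SD 11.2) after 90 min pulses and 381.5 CPM (SD 79.5) in DMSO. It was 288 against 321 CPM at 48 h and 328 against 338 CPM at 72 h. At 24 h DMSO also had the lower mean total, 697589 against 1066190. The most abundant genes, Hes1 among them, tended to go down as the total rose, so depth may contribute to the Hes1 fall at 24 h.

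The level of the secretory progenitor list in each library, as mean log2 CPM, was 6.10 (SD 0.11, n = 9) after 90 min pulses and 5.84 (SD 0.09, n = 9) in DMSO. The difference was 0.26 (SE 0.05), with 9 of 9 treated libraries above the DMSO mean of their duration, and it was 0.33 at 24 h, 0.18 at 48 h and 0.26 at 72 h. The two-sided exact permutation test within durations gave p = 0.00025, the smallest its 8000 arrangements can give, and an adjusted p of 0.0375 over 150 tests. It was the 1 list score of the 150 that passed. The goblet list score was 0.29 (SE 0.07) higher, with 9 of 9 treated libraries above the DMSO mean of their duration, and did not pass (exact permutation p = 0.002, adjusted p = 0.15). The call for secretory progenitors held without 12 of the 18 libraries in turn, with differences between 0.24 and 0.29. It was lost, with the adjusted exact permutation p in brackets, without DMSO 24 h replicate 1 (0.15), 2 (0.1125) and 3 (0.15), DMSO 48 h replicate 3 (0.075) and 90 min 72 h replicates 2 and 3 (0.075 each). It was also lost when the list was taken as log2 of its summed CPM.

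**Figure D1:**
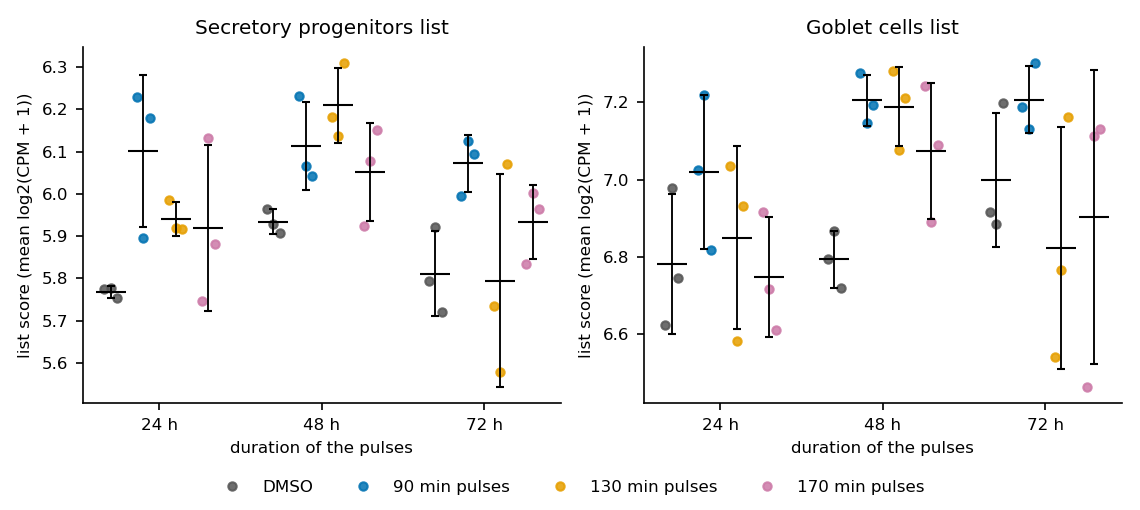
List score of secretory progenitor genes and of goblet cell genes in each of the 36 libraries, as mean log2(CPM + 1) over the list's tested members on the vertical axis, by treatment and by duration in h along the horizontal axis; points are libraries, and lines and bars the mean and SD of 3 replicates. Secretory progenitor scores averaged 6.10 after 90 min pulses and 5.84 in DMSO.

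Relative to DMSO, 5 lists fell after 90 min pulses. Genes of G2 and M phase, which drive mitosis, changed by a mean of -0.09 with 24 of 29 members lower (adjusted p = 1.94e-05, and adjusted p = 0.753 with an estimated correlation). Their 2 highest scores were 7.13 in DMSO 24 h replicate 1, the library with the lowest total, and 7.12 in DMSO 48 h replicate 3, and without these 2 libraries the mean was -0.02 and did not pass (adjusted p = 0.136). S phase genes changed by -0.04 (adjusted p = 0.0329, and adjusted p = 0.884 with an estimated correlation), and did not pass without the same 2 libraries (adjusted p = 0.611), which had their highest scores too (6.77 and 6.85). Cholesterol synthesis genes changed by -0.12 with 22 of 24 lower (adjusted p = 8.47e-07, and adjusted p = 0.753 with an estimated correlation). NF-kB and inflammatory genes changed by -0.23 (adjusted p = 0.00504, and adjusted p = 0.281 with an estimated correlation) and hypoxia and glycolysis genes by -0.08 (adjusted p = 0.0246, and adjusted p = 0.895 with an estimated correlation). Adjusted over the list alone, Tacc3, a spindle protein, fell by 0.29 (SE 0.08), Nfkbia, the inhibitor of NF-kB, fell by 0.26 (SE 0.07), and Klf4, a transcription factor of differentiated epithelium, rose by 0.38 (SE 0.12). The Notch list as a whole (mean -0.05, 5 of 6 members lower, adjusted p = 0.275) and the Lgr5 stem cell list (mean -0.05, adjusted p = 0.102) did not pass, and Lgr5 itself stood at -0.07 (SE 0.17). Nor did Paneth cell genes (mean 0.14), enteroendocrine genes (0.38), M cell genes (-0.07, median 0.02), interferon response genes (0.10) or BMP target genes (0.03). Over all genes 0 passed in edgeR and 0 in DESeq2, with 908 at an unadjusted p under 0.05 in edgeR. These 908 became 285 with log2 of the library total as a covariate and 204 over 48 and 72 h alone. The smallest p-values belonged to Klf11 (0.71, SE 0.16), Cstf2 (-0.34, SE 0.08) and Fam117a (0.55, SE 0.13), each at an adjusted p of 0.543. Panel members Atoh1, the transcription factor that commits cells to the secretory lineage (0.19, SE 0.12), Dll1 (0.25, SE 0.12), Olfm4 (-0.25, SE 0.32), Muc2 (0.16, SE 0.14) and Mki67 (-0.13, SE 0.07) did not pass. Without replicate 1 of every group the hypoxia list mean was 0.08, and without replicates 2 or 3 the S phase list no longer passed (adjusted p = 0.0728 and 0.253).

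After 130 min pulses, 7 lists stood above DMSO and 4 below. The secretory progenitor list rose by a mean of 0.19, with 12 of 13 members higher (adjusted p = 0.00368, and adjusted p = 0.254 with an estimated correlation). The goblet list rose by 0.11 (adjusted p = 0.00504) and the tuft cell list, markers of chemosensory cells, by 0.47 with 11 of 12 members higher (adjusted p = 0.0222). Tuft scores ran from 2.68 to 4.58 after 130 min pulses, highest in 72 h replicate 3. In DMSO they ran from 2.83 to 4.44, highest in 48 h replicate 1. The villus tip list, markers of the oldest enterocytes, rose by 0.40 with 11 of 12 higher (adjusted p = 0.00995). PPAR and fatty acid oxidation genes rose by 0.21 (adjusted p = 0.0216), immediate early and heat shock genes by 0.14 with 14 of 15 higher (adjusted p = 0.0222) and p53 targets by 0.08 (adjusted p = 0.0343). These 6 lists had adjusted p = 0.862 to 0.884 with an estimated correlation. At 72 h the p53 score was 5.85 to 6.37 after 130 min pulses and 5.53 to 5.81 in DMSO. The immediate early and heat shock score was 6.14 to 6.59 and 5.92 to 6.05. At 24 and 48 h the scores of both lists overlapped with those of DMSO. The goblet score was 7.08 to 7.28 against 6.72 to 6.87 in DMSO at 48 h, and 6.54 to 7.16 against 6.88 to 7.20 at 72 h. Lists that fell were G2 and M phase (-0.10, 28 of 29 lower, adjusted p = 1.94e-05), NF-kB and inflammatory genes (-0.21, adjusted p = 0.00368), hypoxia and glycolysis (-0.17, adjusted p = 0.00794) and cholesterol synthesis (-0.07, adjusted p = 0.0306). The NF-kB list had adjusted p = 0.268 with an estimated correlation and the other 3 had adjusted p = 0.753 to 0.895 with an estimated correlation. The highest hypoxia scores were 6.78 and 6.72 in replicate 1 of DMSO at 24 and 72 h and 6.76 in replicate 3 of 130 min at 24 h. Without DMSO 24 h replicate 1 and 48 h replicate 3 the G2 and M phase mean was -0.04 (adjusted p = 0.286). Adjusted over the list alone, Tnf, an inflammatory cytokine, fell by 0.87 (SE 0.22) and Il18, an epithelial cytokine, rose by 0.56 (SE 0.17). Hes1 stood at 0.02 (SE 0.08) and Atoh1 at 0.19 (SE 0.12).

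Over all genes at 130 min, 0 passed in edgeR, with 629 at an unadjusted p under 0.05, and 7 rose in DESeq2. Mtmr14 (-0.65, SE 0.13) and Cstf2 (-0.36, SE 0.08) had an adjusted p of 0.181 and Cyp2c55 (0.59, SE 0.14) one of 0.256. The count was 1 without 130 min 24 h replicate 1, 4 without 130 min 24 h replicate 3, 1 without 130 min 48 h replicate 3 and 2 without 130 min 72 h replicate 2. Without replicate 3 of every group the villus tip mean was -0.18 and the PPAR mean -0.02.

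After 170 min pulses 5 lists stood below DMSO and none above. Fetal-like and YAP target genes, which mark regenerating epithelium, had a mean of -0.23 with 16 of 21 members lower (adjusted p = 0.00614, and adjusted p = 0.895 with an estimated correlation). Their score was 5.39 to 5.86 at 24 h, against 5.83 to 6.64 in DMSO, where replicate 2 was the highest library compared. It was 5.51 to 5.82 against 5.84 to 6.32 at 48 h. At 72 h it was 5.94, 6.54 and 5.68 in replicates 1, 2 and 3 against 5.72 to 5.80, so the fall was not seen there. Genes of Paneth cells, the antimicrobial cells of the crypt base, had a mean of -0.13 with 15 of 18 lower (adjusted p = 0.0424, and adjusted p = 0.895 with an estimated correlation). The Paneth score was 5.30 and 5.98 in replicates 1 and 2 of 170 min at 72 h and 6.53 to 7.31 in the other libraries compared, and without these 2 the mean was 0.07 (adjusted p = 0.835). G2 and M phase genes had a mean of -0.07 (adjusted p = 9.13e-04, and adjusted p = 0.862 with an estimated correlation), and did not pass without DMSO 24 h replicate 1 and 48 h replicate 3 (adjusted p = 0.429). Cholesterol synthesis genes had one of -0.09 (adjusted p = 7.78e-04, and adjusted p = 0.884 with an estimated correlation) and NF-kB genes one of -0.11 (adjusted p = 0.0167, and adjusted p = 0.380 with an estimated correlation). Nfkbia fell by 0.27 (SE 0.07), adjusted over the list alone. All 6 measured Notch list members were lower, with a mean of -0.13 that did not pass (adjusted p = 0.178), and the interferon response list, with a mean of 0.30, did not pass either (adjusted p = 0.382). The secretory progenitor score was 0.13 (SE 0.05) above DMSO and did not pass (exact permutation p = 0.0118, adjusted p = 0.441). Over all genes 0 passed in edgeR and 0 in DESeq2, with 990 at an unadjusted p under 0.05 in edgeR, 260 with log2 of the library total as a covariate and 277 over 48 and 72 h alone. Nfs1 (-0.27, SE 0.06), Cct3 (-0.31, SE 0.07) and Eif4g1 (-0.36, SE 0.09) had the smallest p-values, at an adjusted p of 0.520. With log2 of the library total as a covariate the cholesterol list mean was 0.01, and without replicate 2 of every group the NF-kB list mean was 0.02.

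The periods were compared with one another to ask whether the response depended on the period, with dose changing alongside. Between 90 and 130 min, goblet genes were higher at 90 min by a mean of 0.16 (adjusted p = 0.0209). Enterocyte genes (-0.12, 29 of 39 lower, adjusted p = 0.0216), immediate early genes (-0.11, adjusted p = 0.0246), cholesterol synthesis genes (-0.05, adjusted p = 0.0230) and PPAR genes (-0.19, 17 of 19 lower, adjusted p = 0.00368) were lower. These 5 lists had adjusted p = 0.862 to 0.895 with an estimated correlation. The PPAR score of 130 min replicate 3 was 7.16, 6.71 and 6.86 at 24, 48 and 72 h. It was 5.81 to 6.82 in replicates 1 and 2 of 130 min and 6.20 to 6.64 after 90 min pulses, so the PPAR difference leaned on replicate 3. Hes1 was lower at 90 min by a log2 change of -0.24 (SE 0.08) and passed adjusted over the list alone. The mean library total was 1058610 at 90 min and 855825 at 130 min, and the mitochondrial share of counts 1.02% (SD 0.0896) and 1.20% (SD 0.119). Over all genes 0 passed in edgeR, with 1348 at an unadjusted p under 0.05 (679 with log2 of the library total as a covariate and 655 over 48 and 72 h alone), and 19 were lower in DESeq2. Tom1l1 (-0.29, SE 0.06), Rnf26 (1.02, SE 0.22) and the mitochondrial gene mt-Cytb (-0.43, SE 0.10) led at an adjusted p of 0.263. The count was 1 without 130 min 24 h replicate 1 and 6 without 90 min 24 h replicate 2. Without replicate 3 of every group the enterocyte mean turned to 0.20. Without replicate 2 of 130 and of 170 min at 72 h, 2 libraries with scores apart (4.97 and 5.90), it was -0.28 (adjusted p = 4.01e-08, and adjusted p = 0.730 with an estimated correlation). With log2 of the library total as a covariate the cholesterol mean turned to 0.04.

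Between 170 and 130 min, all 21 measured fetal-like and YAP targets were lower at 170 min, by a mean of -0.40 (adjusted p = 1.26e-04, and adjusted p = 0.862 with an estimated correlation). Their score was 5.39 to 5.86 at 170 min against 5.04 to 6.51 at 130 min at 24 h, and 5.51 to 5.82 against 5.53 to 6.11 at 48 h. At 72 h it was 5.68 to 6.54 against 6.16 to 6.96. Replicate 3 at 24 h went the other way (5.44 against 5.04). Areg, an EGF receptor ligand (-0.51, SE 0.17), Anxa3 (-0.38, SE 0.12) and Cd44, a hyaluronan receptor (-0.26, SE 0.09), passed adjusted over the list alone. Villus tip genes (-0.26, adjusted p = 0.0483), unfolded protein and integrated stress response genes (-0.12, adjusted p = 0.0189), immediate early genes (-0.17, adjusted p = 0.00355) and PPAR genes (-0.22, adjusted p = 0.00597) were lower as well, each with adjusted p = 0.862 or 0.895 with an estimated correlation. Junb (-0.28, SE 0.09) passed adjusted over the list alone, as did Guca2a, the guanylin gene (-0.29, SE 0.09), and Smim14 (-0.20, SE 0.06) of the goblet list. The mean library total was 1093670 at 170 min and 855825 at 130 min, and with log2 of the library total as a covariate the unfolded protein mean was 0.01. Over all genes 0 passed in edgeR, with 1378 at an unadjusted p under 0.05 (575 with log2 of the library total as a covariate and 581 over 48 and 72 h alone), and 32 were lower in DESeq2. Rnf13 (-0.25, SE 0.06), Cnpy3 (0.34, SE 0.08) and Actr10 (-0.21, SE 0.05) had an adjusted p of 0.271.

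The replicate numbers paired the 130 and 170 min libraries: deviations from the group means correlated across genes in all 9 same-numbered pairs, at 0.24 to 0.59, each library best with its own number. With each pair as a block, chosen after the data were seen, 11 genes passed, all lower at 170 min. They were the epithelial surface genes Mucl3 (-1.19, SE 0.20) and Msln, mesothelin (-0.48), Car2, a carbonic anhydrase (-0.44), Areg (-0.52), Anxa3 (-0.38), the transcription factor Foxq1 (-0.36), the long noncoding RNA Neat1 (-0.35), Tm4sf4 (-0.41), Nat8f5 (-0.56), Hmgn3 (-1.24) and Gm19272 (-1.80). In the fit with all 3 covariates Hmgn3 also rose with the summed level of Y-linked genes and with Xist, which was high in only 2 libraries. The log2 differences were 6.55 and 4.82 between a level of 0 and that of the highest library. With pairs as blocks 9 lists passed, all lower at 170 min. They were the 5 above and the Paneth (-0.17, adjusted p = 3.29e-04), enteroendocrine (-0.47, adjusted p = 6.30e-04), enterocyte (-0.07, adjusted p = 0.00284) and goblet lists (-0.05, adjusted p = 0.0271), with adjusted p = 0.551 to 0.676 with an estimated correlation. Without pair 3 at 72 h the enteroendocrine mean turned to 0.20 (adjusted p = 0.969) and the Paneth list, at -0.05, did not pass (adjusted p = 0.0538). The enterocyte and goblet lists each failed without 3 of the 9 pairs in turn, and the villus tip and unfolded protein lists without 2. The count of 11 depended on single pairs: at 24 h it was 42, 0 and 27 without pairs 1, 2 and 3, at 48 h 4, 1 and 1, and at 72 h 25, 26 and 0.

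Between 170 and 90 min, the secretory lists were lower at 170 min. Goblet genes had a mean of -0.22 with 22 of 23 lower (adjusted p = 9.12e-15, and adjusted p = 0.228 with an estimated correlation). Paneth genes had a mean of -0.27 with 17 of 18 lower (adjusted p = 3.73e-06, and adjusted p = 0.753 with an estimated correlation), which was -0.06 without replicates 1 and 2 of 170 min at 72 h and did not pass (adjusted p = 0.485). Secretory progenitor genes stood at -0.12 (adjusted p = 0.0152, and adjusted p = 0.357 with an estimated correlation). Clca1, a secreted goblet protein (-0.46, SE 0.14), Ramp1 (-0.47, SE 0.16) and Fer1l6 (-0.63, SE 0.21) passed adjusted over the list alone. Enteroendocrine genes (-0.26, 23 of 26 lower, adjusted p = 0.00343), fetal-like and YAP targets (-0.31, 20 of 21 lower, adjusted p = 1.94e-05) and gastric or Brunner gland genes (-0.37, 5 of 6 lower, adjusted p = 0.0246) were lower, with adjusted p = 0.753 to 0.895 with an estimated correlation. The goblet score differed by -0.24 (SE 0.10) and did not pass (exact permutation p = 0.0115, adjusted p = 0.441). Over all genes 0 passed in edgeR and 0 in DESeq2, with 149 at an unadjusted p under 0.05 in edgeR, and Sbno2 (-0.38, SE 0.10) had the smallest p-value, followed by Clca1 and Skiv2l (-0.22, SE 0.07). Without replicate 1 of every group the enteroendocrine mean turned to 0.05.

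**Figure D2:**
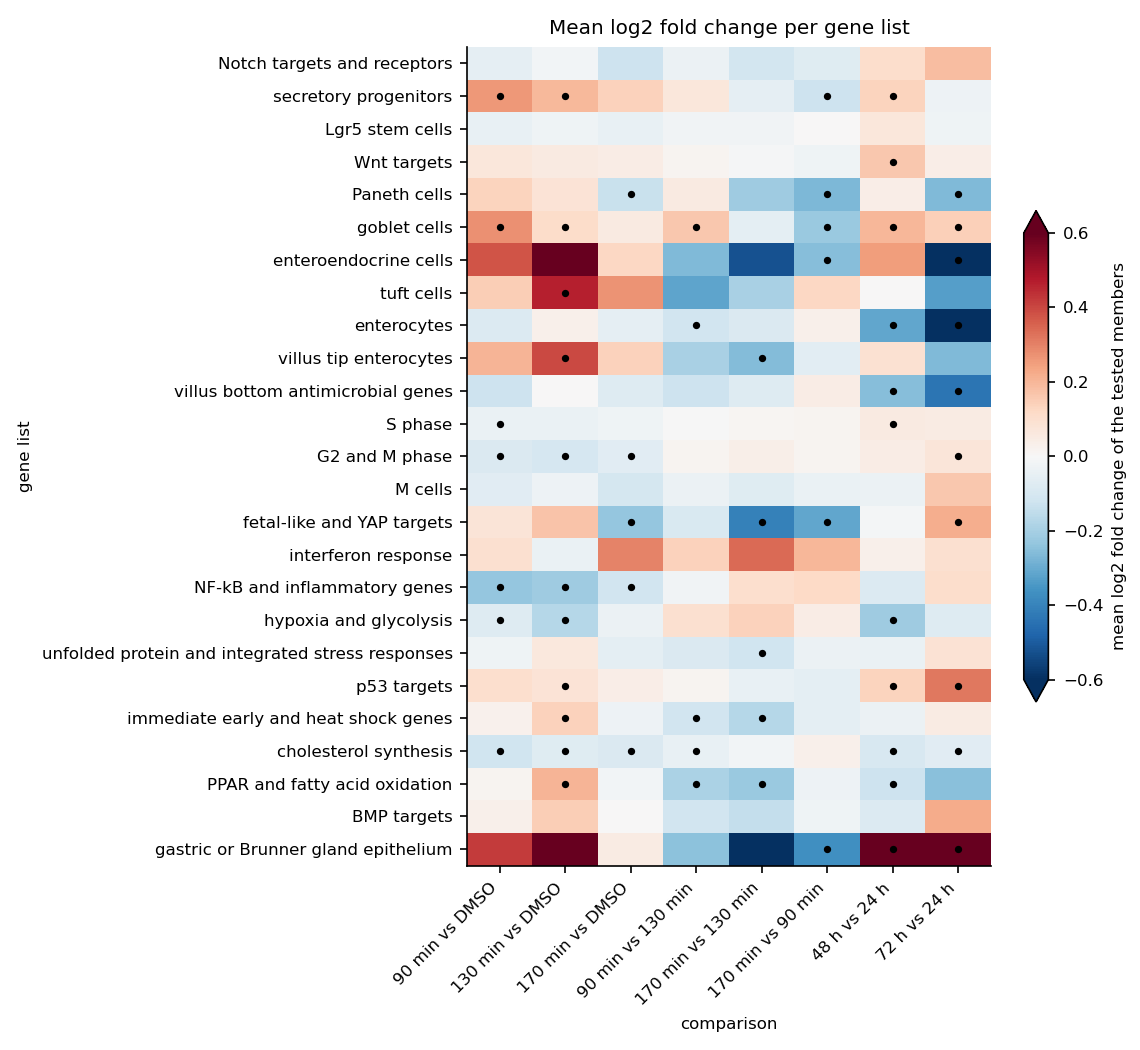
Mean log2 fold change of the tested members of each of the 25 gene lists (vertical axis) in 8 comparisons (horizontal axis), by colour; a dot stands for a camera adjusted p under 0.05 at a preset correlation of 0.01. The goblet list is higher in 90 min pulses than in DMSO by 0.27 and lower in 170 than in 90 min pulses by -0.22.

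At single durations, with 3 libraries against 3, the transcription factor gene Klf11 had the smallest p-value at 24 h for both longer periods, with 1.28 (SE 0.31) above DMSO after 130 min pulses and 1.46 (SE 0.30) after 170 min pulses, and passed in neither. At 24 h, 0 genes passed in edgeR and in DESeq2 for 90, 130 and 170 min, with 1111, 539 and 1421 at an unadjusted p under 0.05 and smallest adjusted p-values of 0.453, 0.965 and 0.312. The mean library totals at 24 h, in the same order as these counts, were 1066190, 873466 and 1179370, against 697589 in DMSO. Periods with a higher mean total had the higher count. Next to Klf11 stood Smc4, a condensin subunit (-0.57), and Mtmr14 (-0.92) for 130 min, Rbm25 (-0.55) and Cfl2 (-0.46) for 170 min, and Adss (-0.44), Usp21 (0.62) and Tmed2 (-0.67) for 90 min. The 170 min count at 24 h was 1 without DMSO 24 h replicate 2 and 1 without DMSO 24 h replicate 3. At 48 h, 0 passed in edgeR and in DESeq2, with 175, 283 and 361 at an unadjusted p under 0.05. The leading genes were Spire2 (0.74), Dll4 (0.80, SE 0.23) and Llph (-0.38) for 90 min, Cyp2c55 (0.94), Noc4l (-0.72) and Vstm5 (-0.94) for 130 min, and Isy1 (-0.44), Fgl2 (1.27) and Las1l (-0.41) for 170 min. At 72 h, 0 passed in edgeR and in DESeq2, with 114, 1179 and 249 at an unadjusted p under 0.05. The leading genes were Rsl1 (1.17), Inip (-0.57) and Bcl6 (-0.69) for 90 min, Ralgapb (0.49) and Rras2 (0.50) for 130 min, where the adjusted p was 0.286, and Nudt16 (-0.73), Atxn2l (-0.85) and Vgll3 (2.40) for 170 min.

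The replicate numbers paired DMSO with 90 min libraries at 24 h (correlations of deviations across genes of 0.138 to 0.427) and at 48 h (0.173 to 0.491), and not at 72 h (0.0863 to 0.116). Libraries of the same number were each other's best match in 1 of 3 pairs at 24 h, 1 of 3 at 48 h and 3 of 3 at 72 h, against 9 of 9 for 130 and 170 min. With each pair as a block, chosen after the data were seen, Fer1l6 was the 1 gene that passed at 48 h, at 1.16 (SE 0.20) above DMSO. At 48 h in that model goblet genes were higher by a mean of 0.41 (adjusted p = 0.00972 with an estimated correlation) and NF-kB genes lower by a mean of -0.29 (adjusted p = 0.0246 with an estimated correlation). At 24 h the goblet mean was 0.22 (adjusted p = 0.0174, and adjusted p = 0.409 with an estimated correlation) and the NF-kB list, at -0.18, did not pass (adjusted p = 0.0998). At 24 h 4 genes passed, Mcf2l (0.99), B020010K11Rik (-0.67) and the pseudogenes Rps26-ps1 (3.25) and Gpx4-ps2 (-0.68), whose reads cannot always be told from those of the parent genes.

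Any difference among the 3 periods was tested at each duration, and a change of the treatment effect with duration by the interaction. Flna, the actin crosslinker filamin A, was among the 3 smallest p-values of the 24 h test, with Rnf26 and Timm8b, and had the smallest p-value of the interaction, followed by Flvcr1, a heme exporter, and Asah2, a ceramidase. Oasl2, Nbeal2 and Enah led at 48 h and Abcb10, Ralgapb and Ist1 at 72 h. In edgeR and in DESeq2 0 genes passed in each of these 4 tests, with 801, 245 and 477 at an unadjusted p under 0.05 in edgeR at 24, 48 and 72 h and 272 for the interaction. The list scores had no interaction that passed (smallest permutation p = 0.0865, adjusted p = 0.964). An effect in 1 group alone cannot give a p under 0.0182 there, too coarse for 1 list to pass over 25, so this leaves such an interaction open.

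Organoids kept on the chip for 72 h were compared with those kept for 24 h, averaged over the 4 treatments, with the total of passage and chip days at 4 in both. Genes of enterocytes, the absorptive cells, fell throughout: all 39 measured members were lower, by a mean of -0.61 (adjusted p = 5.31e-22, and adjusted p = 0.267 with an estimated correlation). The enterocyte score was 4.97 and 5.90 in replicate 2 of 130 and of 170 min at 72 h and 6.64 to 8.20 in the other libraries compared. Without these 2 the mean was -0.43 (adjusted p = 3.34e-16, and adjusted p = 0.274 with an estimated correlation). Of the 39 members, 24 passed adjusted over the list alone, among them Apoa4, an apolipoprotein of dietary fat transport (-1.82, SE 0.38), Enpep, a brush border peptidase (-1.74, SE 0.49), Treh, trehalase (-1.46), Slc51b, a bile acid exporter subunit (-1.28), and Fabp1, a fatty acid binding protein (-1.05, SE 0.24). Gastric or Brunner gland genes rose by a mean of 1.50 with 5 of 6 higher (adjusted p = 4.83e-05, and adjusted p = 0.0940 with an estimated correlation). Adjusted over the list alone 3 of them passed, the gastrokines Gkn1 (3.09, SE 0.63) and Gkn2 (3.20, SE 0.77) and the trefoil factor Tff1 (1.24, SE 0.32). Targets of p53 rose by a mean of 0.32 with 18 of 20 higher (adjusted p = 1.99e-08, and adjusted p = 0.104 with an estimated correlation). Adjusted over the list alone 11 of them rose, including Phlda3 (1.44, SE 0.28), Gdf15 (0.77), Zmat3 (0.61), the death effector Bax (0.49) and the cell cycle inhibitor Cdkn1a (0.31), and Sesn1 (-0.62) fell. Genes at the villus bottom, antimicrobial genes of young enterocytes, had a mean of -0.44 (adjusted p = 1.69e-04, and adjusted p = 0.258 with an estimated correlation), and -0.35 without the same 2 libraries, whose scores of 6.08 and 6.31 were the lowest compared. The lectins Reg3b (-1.45, SE 0.36), Reg3a (-1.37, SE 0.35) and Reg1 (-0.87, SE 0.23) passed adjusted over the list alone.

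Between 72 and 24 h 6 further lists passed. Enteroendocrine genes had a mean of -0.82 with 22 of 26 lower (adjusted p = 0.00135) and cholesterol synthesis genes one of -0.07 (adjusted p = 0.0198). Paneth genes had one of -0.27 (adjusted p = 0.0198). The Paneth mean turned to 0.09 without replicates 1 and 2 of 130 and of 170 min at 72 h (adjusted p = 0.00605, and adjusted p = 0.452 with an estimated correlation). Goblet genes (0.14, adjusted p = 0.0221), G2 and M phase genes (0.07, 26 of 29 higher, adjusted p = 0.00475) and fetal-like and YAP targets (0.22, adjusted p = 0.00163) were higher. These 6 had adjusted p = 0.659 or 0.665 with an estimated correlation. The rise of the fetal-like list was not seen in DMSO, where its score was 5.83 to 6.64 at 24 h and 5.72 to 5.80 at 72 h. At 24 and 72 h it was 5.04 to 6.51 and 6.16 to 6.96 for 130 min. It was 5.39 to 5.86 and 5.68 to 6.54 for 170 min, and 5.38 to 6.53 and 5.62 to 6.67 for 90 min. Adjusted over the list alone, the Notch receptor Notch3 (0.96, SE 0.30), the Notch ligand Jag2 (0.59, SE 0.15), Nfkb2 (0.42), Sesn2 (0.68), Fer1l6 (0.60) and Clca1 (0.38) rose. The fatty acid transporter Cd36 (-1.72, SE 0.48), Ehhadh (-0.77), Tmem37 (-2.08) and the immunoglobulin receptor Pigr (-0.38) fell by the same criterion. Notch targets (mean 0.18, adjusted p = 0.174), Lgr5 stem cells (-0.03, adjusted p = 0.736), M cells (mean 0.16, median -0.01, adjusted p = 0.817), the interferon response (0.10, adjusted p = 0.819) and BMP targets (0.22, adjusted p = 0.159) did not pass here, nor in any other of the 8 comparisons. The summed level of Y-linked genes was 88.8 CPM (SD 103) at 72 h and 171 CPM (SD 184) at 24 h, with 12 libraries each, and with the Y-linked and Xist levels as covariates the enteroendocrine mean was 0.59. Without replicate 3 of every group the goblet mean was -0.02.

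Over all genes 18 passed between 72 and 24 h in edgeR, 6 higher and 12 lower, at adjusted p-values from 0.0252, and 102 in DESeq2. The higher genes were Gkn1, Phlda3, Fgd3 (1.08, SE 0.22), Zmat3 (SE 0.13), the cytochrome P450 Cyp2c55 (0.54, SE 0.12) and Gtf3c1, a subunit of a transcription factor for RNA polymerase III (0.37, SE 0.08). The lower genes with the largest changes were Slc5a11, an inositol cotransporter (-2.78, SE 0.51), Gdpd2, a phosphodiesterase (-2.34, SE 0.44), Gda, guanine deaminase (at 0.250 times its 24 h level), Apoa4, Gchfr, a regulator of tetrahydrobiopterin synthesis (-0.93, SE 0.17), and Fcgrt, the neonatal Fc receptor (-0.85, SE 0.19). The count was 1 with the Y-linked and Xist levels as covariates, 0 without the 2 libraries with the highest Xist level and 3 with only the compared groups in the model. The p-values treat the 24 libraries as independent, while same-numbered libraries of 130 and 170 min deviated together. The count depended on single libraries. Among the 24 h libraries it was 152 and 5 without 130 min replicates 1 and 3, 32 and 0 without 170 min replicates 1 and 3, 0, 85 and 3 without 90 min replicates 1, 2 and 3, and 93 and 0 without DMSO replicates 2 and 3. Among the 72 h libraries it was 1 and 132 without 130 min replicates 2 and 3, 0 and 84 without 170 min replicates 2 and 3, 0, 0 and 32 without 90 min replicates 1, 2 and 3, and 4, 5 and 0 without DMSO replicates 1, 2 and 3.

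**Figure D3:**
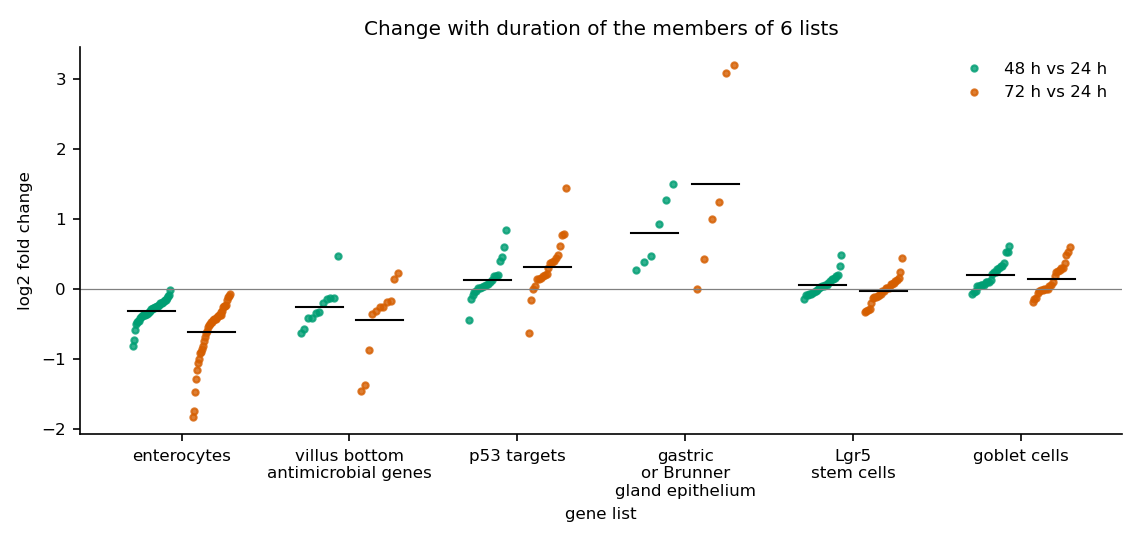
Log2 fold change of each tested member (points) of 6 gene lists at 48 h and at 72 h relative to 24 h, averaged over the 4 treatments, with the vertical axis in log2 units, the lists along the horizontal axis and a line at the list's mean. All 39 enterocyte genes lie below 0 at both durations, with means of -0.31 and -0.61.

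At 48 h relative to 24 h, enterocyte genes were already lower, all 39 of them, by a mean of -0.31 (adjusted p = 1.17e-11, and adjusted p = 0.437 with an estimated correlation). DMSO 48 h replicate 3 had a score of 5.34, against 6.46 to 8.20 in the other libraries compared, and without it the mean was -0.22. Secretory progenitor genes rose by 0.14 (adjusted p = 0.00563, and adjusted p = 0.192 with an estimated correlation) and goblet genes by 0.20 with 20 of 23 higher (adjusted p = 1.59e-06, and adjusted p = 0.306 with an estimated correlation). Adjusted over the list alone, Spdef, a transcription factor of goblet maturation (0.53, SE 0.16), Ramp1 (0.53, SE 0.14) and Tff1 (0.93, SE 0.32) rose. By the same criterion Insig1 (-0.28, SE 0.08), Cyp51, Hmgcs1 and Msmo1 of cholesterol synthesis, Hadhb (-0.20, SE 0.06) and Serpinb1a (-0.22, SE 0.07) fell. Gastric genes rose by 0.81 (6 of 6 higher, adjusted p = 0.00449), Wnt targets by 0.16 (adjusted p = 0.00511), p53 targets by 0.13 (adjusted p = 0.0245) and S phase genes by 0.05 (adjusted p = 0.0422). Villus bottom genes (-0.25, adjusted p = 0.00163), hypoxia genes (-0.21, adjusted p = 6.07e-05), cholesterol synthesis genes (-0.09, adjusted p = 1.75e-05) and PPAR genes (-0.12, adjusted p = 2.12e-04) fell. These 8 lists had adjusted p = 0.258 to 0.659 with an estimated correlation. Over all genes 0 passed in edgeR, with 1104 at an unadjusted p under 0.05, and 12 fell in DESeq2. Nampt (-0.28, SE 0.06), Plac8 (-0.31, SE 0.07) and Plgrkt (-0.24, SE 0.06) had an adjusted p of 0.324. Without replicate 3 of every group the enterocyte mean was -0.06 (adjusted p = 0.143) and the S phase mean 0.01. Without DMSO 24 h replicate 1 and 48 h replicate 3 the S phase list did not pass (adjusted p = 0.0784). The mean Y-linked level was 213 CPM (SD 143) at 48 h.

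Libraries differed widely in sex-linked transcripts and in markers that moved with them. The summed level of 4 Y-linked genes ran from 1.68 to 547 CPM, and Xist, the RNA of the inactive X chromosome, reached 93.9 CPM in replicate 3 of the 130 min and of the 170 min group at 24 h. By treatment the Y-linked mean was 161 CPM in DMSO, 153 after 90 min, 180 after 130 min and 136 after 170 min pulses. In all other libraries Xist was at most 1.60 CPM. The Xist covariate therefore in effect set that 1 same-numbered pair, whose libraries deviated together, against the rest. With both levels as covariates the Y-linked level was associated with 1901 genes and Xist with 746. With log2 of the library total added, these were 2100 and 910. In the fit with all 3 covariates Chga, Sst and Gip, enteroendocrine genes, rose with the Y-linked level by log2 differences of 6.12, 7.15 and 6.82. These are differences between a level of 0 and that of the highest library. With Xist the same genes rose by 5.11, 5.32 and 5.17. Replicate 3 of 130 min at 24 h, with 1.68 CPM of Y-linked genes and high Xist, had 77 Chga, 97 Sst and 42 Gip counts. Tff2, a gastric and Brunner gland trefoil factor, and Fgf15, an enterokine, changed by -5.12 and -4.74 with the Y-linked level. With Xist they changed by -4.31 and -2.03, and Fgf15 did not pass there. As the only covariate, the log2 of the library total was associated with 1823 genes. The median log2 slope per doubling of the total ran from 0.39 for genes with a mean under 16 counts to -0.33 for the most abundant genes. The share of counts taken by the 500 most abundant genes, 18.1% to 23.2%, correlated with the log2 total over the 36 libraries (Pearson's r = -0.890 and Spearman's rho = -0.863, permutation p = 1e-05 each, the smallest they can give; r = -0.846 without the 2 libraries farthest from the median). Genes of fibroblasts, immune cells and endothelium were too few to test, with 1, 0 and 1 members past the filter and means of 14.2, 8.31 and 34.2 counts per library for each whole list.

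**Figure D4:**
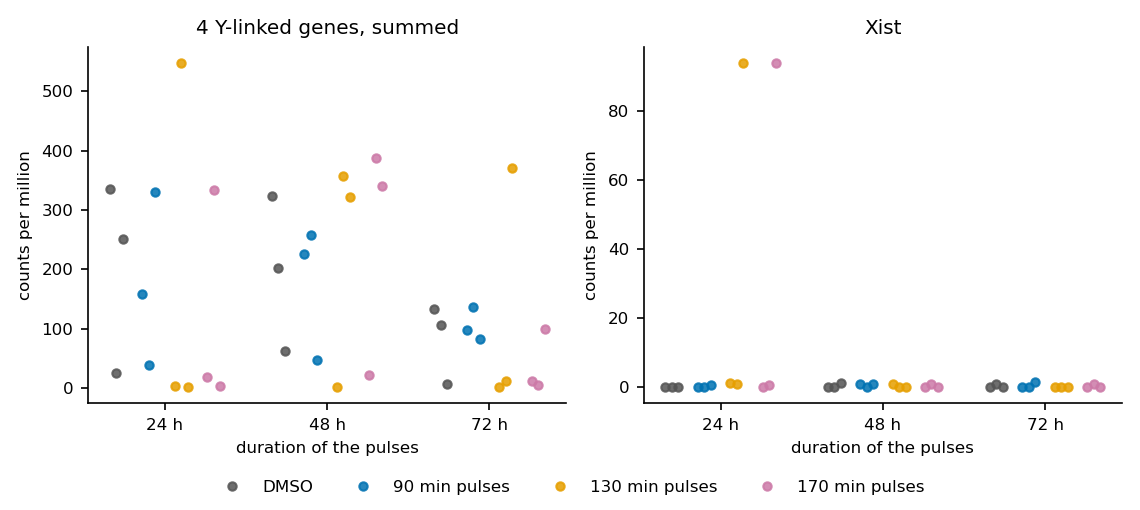
Summed CPM of 4 Y-linked genes and CPM of Xist in each of the 36 libraries (vertical axes), by treatment and by duration along the horizontal axis; each point is a library. Y-linked levels run from 1.68 to 547 CPM for 130 min and from 4.03 to 388 CPM for 170 min pulses. They run from 7.40 to 335 CPM in DMSO and from 39.3 to 331 CPM for 90 min pulses, and Xist reaches 93.9 CPM in 2 libraries.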

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

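Covariates, the 2 left-out Xist libraries, the within-duration block, sign flips, thinned counts, averages over 48 and 72 h, list scores without single libraries and lists without the libraries whose scores stand apart were chosen after the data were seen. Of 104 values of the gene counts under the settings fixed in advance other than leaving out libraries, 80 lay within 1.5 times the reported count. RLE size factors and the plain replicate block (72 h: 18 and 12 genes) changed no count of genes past the threshold by more than that, nor did log2 of the library total (72 h: 12), with which the genes at an unadjusted p under 0.05 fell from 908 to 285 and from 990 to 260 for 90 and 170 min against DMSO. Where the cause is not named below, the cause was not tested.

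Without a filter 34197 genes were tested, and 16 comparisons gained genes. The counts against DMSO became 1 (90 min), 4 (130 min) and 2 (170 min) averaged, 1 (130 min) and 4 (170 min) at 24 h, 2 (170 min) at 48 h, and 52 (130 min) and 1 (170 min) at 72 h. They became 6 for 90 against 130 min, 7 for 170 against 130 min, 10, 4 and 15 for any period at 24, 48 and 72 h, 15 for the interaction, 7 for 48 h and 304 for 72 h against 24 h. DESeq2, which kept fewer genes in some comparisons, called 7 (130 min against DMSO), 19 (90 against 130 min), 32 (170 against 130 min), 12 (48 h) and 102 (72 h). With only the compared groups the counts at 72 h against DMSO were 18 (130 min) and 1 (170 min), and that of 72 against 24 h was 3.

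With Y-linked and Xist levels as covariates 90 against 130 min had 2 genes and 72 against 24 h 1. With all 3 covariates these were 1 and 4, 130 min against DMSO at 72 h had 9, and 13 duration lists passed. Without the 2 Xist libraries 130 min against DMSO had 9 and 72 against 24 h 0. The block within duration gave 21 genes for 90 min against DMSO averaged, 4 at 24 h and 1 at 48 h. It gave 11 for 170 against 130 min. For DMSO with 90 min at 72 h the correlations were not above 0.1 in every pair, although 3 of 3 pairs were each other's best match. List calls were 0 and 0 (treatments and durations) with an estimated correlation and 1 and 3 with fry, which called secretory progenitors for 90 min against DMSO and at 48 h and p53 and gastric lists at 72 h. List scores that passed were 0 with the summed CPM. With sign flips 0 passed, where exact p = 0.0039 is the smallest that 512 flips can give, too coarse for 1 list alone to pass over 150 tests.

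Leaving out libraries gave 0 to 4 genes for 130 min against DMSO, 0 to 6 for 90 against 130 min, 0 to 1 for 170 min against DMSO at 24 h, 0 to 152 for 72 against 24 h, and 0 to 0 for the others. It gave 0 to 1 list scores. Without replicate 1, 2 or 3 of every group, 12 libraries at a time, 36 to 47 treatment lists and 13 to 27 duration lists passed.

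Some list means turned. Without replicates 1, 2 or 3 the lowest and highest were -0.694 and 0.0548 for enteroendocrine genes (170 against 90 min), -0.180 and 0.693 for villus tip and -0.0225 and 0.312 for PPAR genes (130 min against DMSO), and -0.370 and 0.205 for enterocytes (90 against 130 min). For S phase genes at 48 h they were 0.00942, where the direction of the test turned, and 0.116, and for goblet genes at 72 h -0.0162 and 0.275. With log2 of the library total cholesterol genes were at 0.0105 (170 min against DMSO) and 0.0377 (90 against 130 min) and unfolded protein genes at 0.0118 (170 against 130 min). With Y-linked and Xist levels enteroendocrine genes were at 0.594 (72 h). With all 3, enterocyte and cholesterol genes were at 0.0723 and 0.0514 (90 against 130 min), unfolded protein genes at -0.0110 (170 against 130 min, where the direction of the test turned) and enteroendocrine genes at 0.602 (72 h). Without replicates 1 and 2 of 170 min at 72 h Paneth genes were at 0.0722 (170 min against DMSO). Without these and the same replicates of 130 min they were at 0.0726 there and at 0.0867 for 72 against 24 h. With 3 libraries against 3 at 24 h 20.4% of simulated 1.5-fold changes were recovered for 90 min against DMSO, and 63.6% averaged over durations.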

Other observations

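The blocked comparisons, their splits, the splits that keep same-numbered libraries together, the enterocyte list without 2 libraries, the 2 sets of pairs on their own and the tests with depth, Y-linked and Xist levels were chosen after the data were seen, while the splits of the 21 gene counts were chosen in advance.

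Where the deviations of same-numbered DMSO and 90 min libraries correlated above 0.1, at 24 and 48 h, with 1 of 3 pairs each other's best match at each, 15 genes passed with each of the 6 pairs as a block and the 2 durations averaged, 10 of them higher after 90 min pulses. Among these were Dll4, a Notch ligand (0.72, SE 0.14), Fer1l6 (0.92, SE 0.15) of the goblet list, Muc3a, a membrane mucin (0.47, SE 0.10), Tff2, a trefoil factor (1.04, SE 0.21), Klf4, a transcription factor of differentiated epithelium (0.52, SE 0.11), and Rgs2, a regulator of G protein signalling (0.83, SE 0.15). The others were Mcf2l (0.66), Dmpk (0.92), Fam117a (0.65) and the pseudogene Rps26-ps1 (1.90). Lower were Duox2, an epithelial oxidase (-0.64, SE 0.12), Tacc3, a spindle protein (-0.38, SE 0.08), the Paneth cell defensin Defa17 (-0.56, SE 0.11), B020010K11Rik (-0.48) and the pseudogene Gpx4-ps2 (-0.39). Reads of pseudogenes and of defensins, which have close paralogs, cannot always be assigned to 1 gene. In the fit with all 3 covariates Tff2 also went down with the Y-linked level and with Xist, which was high in only 2 libraries. The changes were -5.12 and -4.31 on the log2 scale up to the highest library. The 15 genes were the highest count among the 32 splits that part every pair: 1 split, the real one, gave as many, and the highest other gave 12, a share under 0.05 for a block chosen after the data were seen. The count depended on single pairs, with 3, 142 and 4 genes without pairs 1, 2 and 3 at 24 h and 10, 14 and 4 without pairs 1, 2 and 3 at 48 h.

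In the same model 9 lists passed, adjusted over the lists of this comparison alone, 3 higher and 6 lower after 90 min pulses. The goblet list was higher by a mean of 0.31 (adjusted p = 2.05e-10, and adjusted p = 0.0562 with an estimated correlation) and the secretory progenitor list by 0.26 (adjusted p = 9.47e-04, and adjusted p = 0.209 with an estimated correlation). NF-kB and inflammatory genes had a mean of -0.24 (adjusted p = 5.90e-04, and adjusted p = 0.104 with an estimated correlation). Cholesterol synthesis (-0.12, adjusted p = 7.98e-05), G2 and M phase (-0.09, adjusted p = 1.41e-04) and S phase genes (-0.07, adjusted p = 0.00340) were lower, each with adjusted p = 0.460 with an estimated correlation. So were Lgr5 stem cell (-0.06, adjusted p = 0.0183) and fetal-like and YAP target genes (-0.11, adjusted p = 0.0405), while gastric or Brunner gland genes were higher (0.38, adjusted p = 0.0460). These 3 had adjusted p = 0.319 to 0.776 with an estimated correlation. The S phase list failed without 1 of the 6 pairs in turn, the Lgr5 and fetal-like lists each without 3 and the gastric list without 4.

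The higher level of secretory progenitor and goblet genes after 90 min pulses was weighed against library depth and a mix of source organoids, read from the Y-linked and Xist levels. The secretory progenitor difference of 0.258 was 0.228 (SE 0.064) with log2 of the library total in the model and 0.261 (SE 0.053) with the sex-linked levels. The goblet difference of 0.285 was 0.293 (SE 0.105) and 0.283 (SE 0.093). Each stayed above 0.5 of its size by more than 1 SE, so neither measure accounts for the whole of either difference. A shift towards the secretory lineage may underlie the pattern, as a hypothesis found on these data that neither measure tests. The dose of DAPT, which differs with the period, remains open and untested.

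Lower enterocyte genes at 72 h than at 24 h were weighed against the same measures. The list score difference of -0.651 (SE 0.223) was -0.651 (SE 0.227) with log2 of the library total, so depth does not account for it. It was -0.451 (SE 0.246) with the sex-linked levels, and the mix of source organoids and the time on the chip cannot be told apart, because 1 SE around this value includes 0.5 of the first difference. Part of the difference lay in 2 libraries, replicate 2 of 130 and of 170 min at 72 h, without which the list mean moved from -0.61 to -0.43. The time since passage, which was shorter before the longer experiments, is confounded with the duration and stays open as well.

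Same-numbered libraries of 130 and 170 min deviated together from their group means, with a mean correlation of 0.419 (SE 0.0399) over 9 pairs, against 0.215 (SE 0.0492) for DMSO with 90 min, which were not paired at 72 h. With log2 of the library total regressed out these were 0.438 (SE 0.0423) and 0.194 (SE 0.0671), and 0.316 (SE 0.0486) against 0.317 over all 18 pairs, so depth does not account for either. With the Y-linked and Xist levels regressed out the mean correlation of 130 with 170 min dropped to -0.0206 (SE 0.139), and that of all 18 pairs to 0.0459 (SE 0.0703). The SE for 130 with 170 min was wider than before, so single pairs still spread widely around 0. The mean therefore does not show that these levels account for each pair. The labels do not say whether chips were loaded in parallel from 1 organoid stock. For DMSO with 90 min the mean correlation was 0.112 (SE 0.0220). A mix of source organoids and other causes cannot be told apart there, because 1 SE around this value includes 0.5 of the first. Low Y-linked levels did not come with high Xist in every library (1.76 CPM and 0 CPM in replicate 1 of 130 min at 72 h). What else differed between the source organoids of the libraries was not tested.

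The reported counts were set against other splits of the same libraries. For 72 against 24 h, 1 of 100 splits, the real one, gave 18 genes or more and the highest other gave 6, with libraries exchanged between durations within treatments. Those splits part same-numbered libraries, which deviate together. With same-numbered libraries kept together 8 of 100 splits gave 18 or more, the real one included, and the highest other gave 830, so chance cannot be excluded for that count. For the 11 genes of 170 against 130 min with pairs as blocks, 3 of 100 splits that part every pair gave as many, the real one included, and the highest other gave 19. That share is under 0.05, for a block chosen after the data were seen and a count that was 0 without single pairs. Elsewhere the real count was 0, so all 100 of 100 splits gave as many whatever the cause, and the splits do not bear on chance. The highest other counts were 3, 2 and 1 for 90, 130 and 170 min against DMSO averaged over durations, 1 for 90 against 130 min, 347 for 170 against 130 min, 0 for 170 against 90 min, 76, 0 and 7 for any period at 24, 48 and 72 h, 23 for the interaction and 21 for 48 against 24 h. Why some splits called 347, 76, 23 or 21 genes where the real one called 0 was not tested.

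For each period against DMSO at 24, 48 and 72 h the 10 splits are too few for a share under 0.05. All 10 gave at least the real count of 0, as any split does, and the highest other was 1 for 130 min at 24 h and 0 for the other 8. With pairs as blocks the 4 splits of 90 min against DMSO are also too few: at 24 h the real count was 4 and the highest other 3, with 1 split as large, and at 48 h the real count was 1 and the highest other 2, with 3 splits as large.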
